A study of Mus musculus with 24 samples.

How the data were processed

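Gene expression in epididymal white fat of male C57BL6/J mice was compared between animals fed ad libitum (AL), animals on 40% dietary restriction (DR) and animals given rapamycin at 14 ppm (Rapa). Rapamycin is an inhibitor of the mTOR kinase complex 1. Per the labels, treatment began at 2 months of age and lasted 6 months, so that tissue was taken at 8 months, and each group holds 8 samples. The labels name each sample separately but do not state that each came from its own animal, so p-values measure the spread between these samples. Per the labels, RNA was isolated with a Qiagen RNeasy kit from 25 mg of tissue, made into biotinylated cRNA with an Illumina TotalPrep kit and hybridised to an Illumina mouse BeadChip, with 1 array per sample. The source field and the design text name epididymal fat, whereas the tissue field and the extraction protocol name liver, and the detection of marker genes of both tissues was therefore examined on every array.

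The deposited intensity values cover 45281 probes on each of the 24 arrays and were already background-subtracted, since between 26.7% and 34.3% of the values of an array lie below 0. The scanner software and its settings are not given in the sources used here. The deposited table also holds a detection p-value for each probe and array, per the file headers. A further deposited table holds the authors' processed score for each probe and array. Comparison with the intensities showed that this score is a z-score of the logarithm of intensity plus a constant, computed within each array, with mean 0 and SD 1. The constant lay between 99.0 and 188.8 and the largest deviation of the authors' score from this form was 0.00177. The medians of the authors' score columns lay between -0.42 and -0.32, and no normalization between arrays beyond this scaling was found. The base of the logarithm cannot be read from a z-score, and the authors' score was used only as an alternative.

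Intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc was applied with an offset of 16. It estimated the background from the detection p-values, corrected it by a normal-exponential model, quantile-normalized the arrays and took log2. Probes with a detection p under 0.05 on at least 8 arrays were kept, which left 17165 probes. Gene symbols came from the platform annotation, in which 34885 probes have 1 symbol, 18 have several and 10378 are not listed. An update of symbols through a mouse gene table of the GRCm38.p6 assembly changed 0 symbols. Of the kept probes, 14717 have 1 symbol and 2448 are unnamed here. A gene was represented by its kept probe with the highest mean over all arrays, giving 9836 genes, of which 3455 have more than 1 kept probe. A gene detected on no array of a group has only a bound there, and its change is given as at least a fold, from the bright group's mean against the mean, over arrays of the dim group, of the lowest detected signal of each array or the gene's own value where that was higher. A gene detected on some arrays of a group is given its fitted change, although values near the background limit how exactly such a change is known.

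All 24 arrays entered a single limma fit of group means with 21 residual degrees of freedom. DR was compared with AL, Rapa with AL, and DR with Rapa. The moderated test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over all kept probes, and a gene was called at an adjusted p under 0.05. Adjusted p-values given for genes are from limma, fold changes are on the log2 scale with the standard error (SE) of the fit, and group levels are mean log2 intensity with SD (n = 8). Array number limits the precision. In data simulated from these arrays, with 9836 genes of which 50 were changed at each size, the fit recovered 36% of 1.5-fold and 86% of 2-fold changes for DR against AL, 28% and 72% for Rapa against AL, and 26% and 84% for DR against Rapa. False calls numbered 3 of 161, 6 of 154 and 4 of 156 in these simulations. The simulated noise was normal and independent between probes and arrays, so these rates leave out structure shared by genes and arrays in the real data.

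The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 32 lists cover lipid metabolism (de novo lipogenesis, triglyceride synthesis and storage, lipolysis, fatty acid beta-oxidation, cholesterol biosynthesis), energy metabolism (TCA cycle, oxidative phosphorylation, glycolysis and glucose uptake), growth and stress (cytosolic ribosomal proteins, mTOR pathway components, autophagy and lysosome, ATF4 targets and amino acid synthesis, endoplasmic reticulum chaperones, NRF2 targets and antioxidants, insulin, IGF1 and FOXO signalling, cell cycle, innate interferon response), the circadian clock, fat biology (brown and beige adipocytes, fat-mass-associated adipokines, adipocyte markers), the extracellular matrix, inflammatory mediators, and markers of macrophages, lymphocytes, fibroblasts and progenitors, endothelium, mesothelium, epididymis and testis, hepatocytes, skeletal muscle and erythrocytes. Of 666 entries, 595 have a probe on the array and 485 were kept. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists within a comparison. The test asks whether the list's genes moved relative to the other genes. Camera with an estimated correlation and fry were the alternatives. Member counts are given over all genes tested and adjusted over the list alone.

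The named genes were fixed by rule. For DR against AL and Rapa against AL they are the 10 called genes with the largest change in each direction, or all called genes where fewer passed, leaving out clone and predicted names. For DR against Rapa they are the 5 largest in each direction. Each list contributes up to 4 members, those called in DR against AL with the largest change, or up to 2 with the largest change where none was called. Lep, Adipoq, Fasn, Pparg, Pck1, Ucp1, Igf1, Mtor, Rps6kb1, Eif4ebp1 and Fkbp1a were named whatever their result. Other genes in the text were chosen after their values were seen and are introduced as such.

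Detected probes per array numbered between 13012 and 19203 (28.7% to 42.4%). The 75th percentile of intensity lay between 15 and 111.7. It followed the replicate number, with a mean of 21.5 for numbers 1 and 5, 90.3 for numbers 2 and 6, 47.2 for numbers 3 and 7 and 51.1 for numbers 4 and 8 (6 arrays each, F = 57.0, permutation p = 1e-04, the smallest that 9999 shuffles can give). These 4 number classes hold 2 arrays of every group. The class was added as a block, and values within classes were computed. No 2 arrays held identical values, and the highest rank correlation between arrays was 0.828.

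Alternatives chosen in advance were no background correction, median scaling in place of quantile normalization, the authors' score, no probe filter, probes detected on all 24 arrays, only the 16 arrays compared, the replicate number as a block, array weights, the mean of all probes of a gene, trended and robust variance, a threshold of 0.01, a minimum change of 1.5-fold, and omission of each array. Alternatives chosen after seeing the data were the number class as a block, the median log2 intensity of the epididymis and testis markers (the marker score) as a covariate, both together, and omission of the 7 arrays with a marker score above 6, with and without the class block. Figures were drawn with matplotlib 3.10.9. Unnamed probes were tested but not named, and BeadChip identity was not used because no source used here gives it.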

Results

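The series measured messenger RNA on 24 arrays of mouse epididymal fat, with 8 arrays each for ad libitum feeding (AL), 40% dietary restriction (DR) and 14 ppm rapamycin (Rapa), all at 8 months of age after 6 months of treatment. The 75th percentile of background-subtracted intensity was 62.1 ± 31.0 in AL, 44.1 ± 22.4 in DR and 51.4 ± 30.3 in Rapa (SD, n = 8), and the arrays detected 16834 ± 1444, 15497 ± 1515 and 16309 ± 1852 probes. The design asks how each treatment altered the adipose transcriptome, and the title of the series sets rapamycin against restriction.

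Because the labels name both epididymal fat and liver, the detection of marker genes of both was read on every array. Of 17 adipocyte genes on the array, 15 were detected on all arrays. They include leptin (Lep), the fat-mass hormone, with a mean of 14.25 ± 0.73 (SD, n = 24), Car3, the carbonic anhydrase abundant in adipocytes, and adiponectin (Adipoq). Alb and Fgb, the liver's albumin and fibrinogen beta chain, were detected on 0 arrays. Of 20 hepatocyte genes on the array 6 were detected on no array and 1 on all, and others on some arrays, such as the apolipoprotein Apoa1 and the transport protein Ttr on 8 each. That gene, Cyp2e1, is a cytochrome P450 that white fat also expresses.

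Markers of epididymis and testis, organs that lie against this fat pad, were present on some arrays. The median of these markers (the marker score) was 5.13 ± 0.39 in AL, 6.55 ± 1.498 in DR and 6.31 ± 2.25 in Rapa (SD, n = 8). It exceeded 6 on 4 DR arrays (DR1 at 7.26, DR3 at 6.54, DR5 at 9.34 and DR8 at 7.83), on 3 Rapa arrays (Rapa6 at 9.43, Rapa7 at 6.30 and Rapa8 at 10.24) and on 0 AL arrays, where the highest was 5.78. Abundant members reached high levels on those arrays. Wfdc10, a protease inhibitor of the epididymis, reached 14.48 on Rapa8, and Prm1, the protamine that packs sperm DNA, reached 12.29 there. Arrays below the limit carried such transcripts too. DR7 had a set of epididymal genes, among them the lipocalin Lcn8 at 11.58, Gpx5 at 9.77, Adam7 at 9.45 and the defensin Defb42 at 9.30. AL7 had the testis genes Prm1 at 11.72, Ldhc at 9.69 and Tnp1 at 9.34, and AL6 had Defb42 at 12.49. Values without these 7 arrays are given below where a list's call changed or a called list's median moved by over 1.5 times, and for some other groups.

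**Figure D1:**
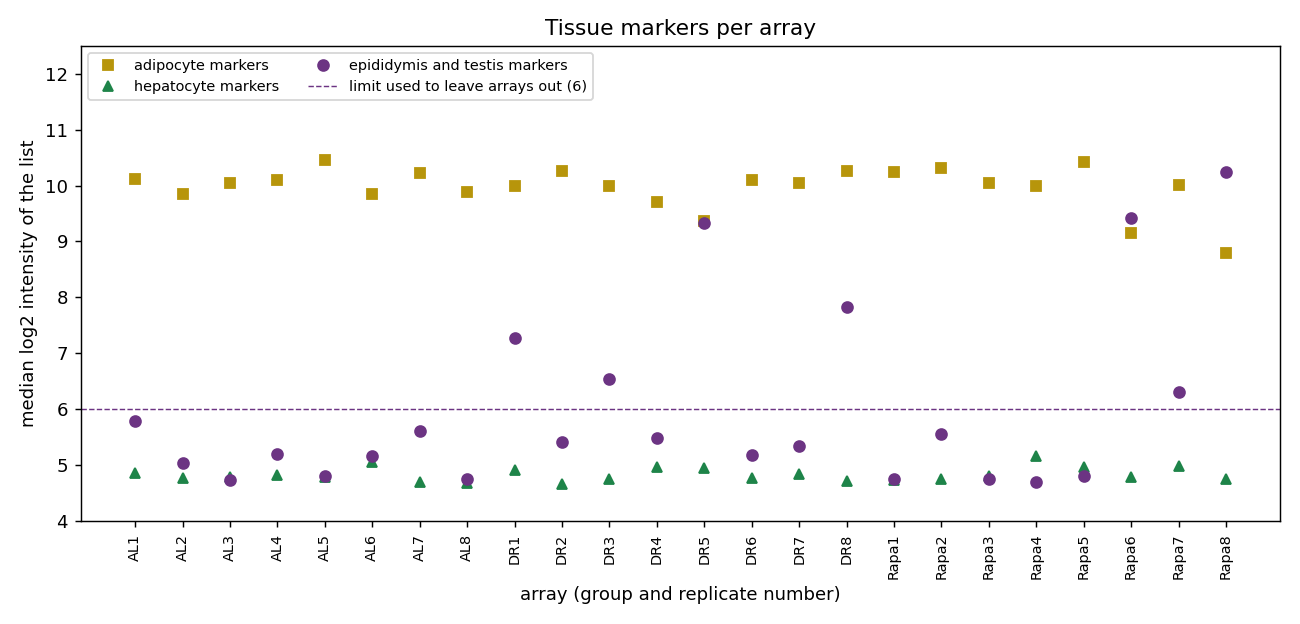
Median log2 intensity of adipocyte, hepatocyte, and epididymis and testis markers on each of the 24 arrays, grouped by AL, DR and Rapa, with a line at the marker score of 6. Adipocyte medians lie at 8.79 or above and hepatocyte medians at 5.16 or below, while 4 DR and 3 Rapa arrays lie above the line.

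Dietary restriction changed fat-making, clock, leptin, matrix and macrophage genes, with the matrix list at adjusted p = 0.0568 and the macrophage list at adjusted p = 0.333 with an estimated correlation. Elovl6, the elongase that extends palmitate, rose from 7.86 ± 0.64 in AL to 11.58 ± 0.55 in DR (SD, n = 8 each), a log2 fold change of 3.72 ± 0.35 (SE, adjusted p = 7.50e-08), with 8 of 8 DR arrays above every AL array. Acly, which makes cytosolic acetyl-CoA from citrate, rose by 1.44 ± 0.18 (adjusted p = 4.32e-06). Dbp, a transcription factor driven by the circadian clock, rose by 2.89 ± 0.29 (adjusted p = 1.59e-07). Lep fell from 14.82 ± 0.23 to 13.29 ± 0.24 (log2 fold change -1.53 ± 0.13, adjusted p = 1.55e-08). Mmp12, the macrophage elastase, changed by -3.40 ± 0.41 (adjusted p = 3.08e-06) and Sparc, a collagen-binding matrix protein, by -1.23 ± 0.18 (adjusted p = 4.29e-05), each with 8 of 8 DR arrays below every AL array. For Mmp12 the DR arrays other than DR7 stood at 5.19 or below, in the range of undetected probes, so the size of its fall is less certain.

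In total 1150 of 9836 genes (11.7%) differed between DR and AL, 511 higher and 639 lower (1817 probes), and 949 of them by at least 1.5-fold. Higher genes were 44.4% of the calls, against 35.8% with the authors' score and 52.6% with median scaling. With the number class as a block 1953 genes passed (912 higher, 1041 lower), among them all 1150. Within the 4 classes between 98.4% and 100% of the 1150 kept their sign. That share is raised by calling the genes on the same arrays. Within single classes, with 2 arrays per group, limma called between 0 and 150 genes. Without the 7 arrays above the marker score of 6, 676 genes passed, 588 of them among the 1150. All 1150 kept their direction there, on arrays that had also given the calls. Of 82 named genes called in this comparison, 20 lost the call on omission of some array, most often Rictor (18 of 24 fits), Rpl22 and Defb37 (16 each), Sc5d (13) and Hcar2 (12). Without the 7 arrays 25 of the 82 were no longer past the threshold, with fewer arrays in the fit.

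Beyond those already given, the genes with the largest rise included Acsm3, a medium-chain acyl-CoA synthetase, at 4.03 ± 0.41 (adjusted p = 2.37e-07), Ciart, a repressor in the clock, at 3.03 ± 0.27 (adjusted p = 3.80e-08). Pcsk4, a proprotein convertase known from germ cells, rose by 2.84 ± 0.19 (adjusted p = 1.52e-10), for which all 4 kept probes passed. Its change was nearly the same without the 7 arrays (2.82, adjusted p = 6.54e-07). Of the genes with the largest rise, 5 are known from the epididymis. They rose by 4.25 ± 1.24 (Wfdc10), 3.97 ± 1.17 (Adam7), 3.80 ± 0.87 (Defb20), 3.77 ± 1.23 (Defb37) and 2.85 ± 0.89 (Spag11b). Defb37 was detected on no AL array, and its rise is at least 10.2-fold. With the 7 arrays left out Wfdc10 stood at 2.06 (adjusted p = 0.0755), Adam7 at 1.84 (adjusted p = 0.122) and Defb37 at 1.66 (adjusted p = 0.0727). Defb20 at 2.36 (adjusted p = 0.0415) and Spag11b at 2.18 (adjusted p = 0.0339) kept their calls there, but DR7, which was not left out, stood at 11.18 for Defb20 and 10.50 for Spag11b. Spag11b lost its call in 10 of 24 fits that each left out an array, DR7 among them. The largest falls were those of Slc5a7, the high-affinity choline transporter, which was detected on all AL arrays and on 0 DR arrays and fell at least 10.6-fold (adjusted p = 3.00e-09), and of Rnase2a, an eosinophil-type ribonuclease, at -3.79 ± 0.50 (adjusted p = 1.12e-05). They were followed by Tph2, a tryptophan hydroxylase, at -3.36 ± 0.58, Ubd, a ubiquitin-like modifier, at -3.30 ± 0.58, Lipf, gastric lipase, at -3.08 ± 0.35, Sfrp5, a secreted Wnt antagonist, at -3.06 ± 0.31, and Hspb7, a small heat shock protein, at -2.37 ± 0.23 (adjusted p of 3.32e-04 or below for each).

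Genes of de novo lipogenesis, which builds fatty acids from acetyl-CoA, rose as a group. Of 14 measured, 7 were higher and 1 lower over all genes tested, and 10 higher and 1 lower adjusted over the list alone. Their median log2 fold change was 0.86 (camera adjusted p = 7.69e-07, and adjusted p = 0.0382 with an estimated correlation), and 1.12 without the 7 arrays. Acss2, which makes acetyl-CoA from acetate, rose by 1.55 ± 0.22. The member that fell, Pnpla3 at -2.00 ± 0.38 (adjusted p = 7.68e-04), encodes a lipid-droplet protein that acts on stored lipid and not a step of fatty acid synthesis. Fasn, fatty acid synthase, stood at 0.93 ± 0.35 and did not pass (adjusted p = 0.0958), but passed with the number class as a block (adjusted p = 0.0278). In triglyceride synthesis and storage 4 of 15 were higher (5 higher and 1 lower adjusted over the list alone). These were Pck1, the glyceroneogenic carboxykinase, at 1.59 ± 0.40, Slc27a1, a fatty acid transporter, at 1.30 ± 0.24, Gpam, the first acyltransferase of the pathway, at 1.00 ± 0.16, and Lpin1, a phosphatidate phosphatase, at 0.91 ± 0.20. That list as a whole had a median of 0.14 and did not pass (camera adjusted p = 0.0513), and without the 7 arrays it passed at 0.34 (adjusted p = 8.37e-04).

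Mitochondrial lists rose by less. In the TCA cycle list 4 of 19 were higher (5 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.0116, and adjusted p = 0.424 with an estimated correlation) and 0.45 without the 7 arrays. The members past the threshold were Pdha1 at 1.15 ± 0.18 and Dlat at 0.66 ± 0.15, subunits of pyruvate dehydrogenase, Pcx, pyruvate carboxylase, at 0.97 ± 0.21, and Suclg2, a succinyl-CoA ligase subunit, at 0.64 ± 0.20. Of these, 3 act on pyruvate before the cycle itself. Suclg2 did not pass with the marker score as a covariate (0.62, adjusted p = 0.0662), whereas without the 7 arrays it stood at 0.93 (adjusted p = 0.00919). Oxidative phosphorylation genes were higher in 5 of 38 (8 adjusted over the list alone), with a median of 0.26 (camera adjusted p = 1.74e-05, and adjusted p = 0.0155 with an estimated correlation). Ndufs7, a complex I subunit, rose by 0.50 ± 0.14 and Uqcrc2, a complex III subunit, by 0.48 ± 0.13.

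The circadian clock list had the largest median shift among the lists called here that rose, apart from the epididymis and testis markers. Of 12 measured genes 9 were higher and 2 lower, with the same counts adjusted over the list alone and a median of 1.30 (camera adjusted p = 7.69e-07, and adjusted p = 0.0127 with an estimated correlation). Per3 rose by 1.99 ± 0.26 and Tef, an output factor related to Dbp, by 1.80 ± 0.30. The genes that fell, Arntl at -1.68 ± 0.22 and Clock at -0.82 ± 0.14, encode the paired activators of the loop. They lie outside the rule for named genes and were chosen after their values were seen. Within the 4 number classes the list median was 1.19, 1.80, 1.07 and 1.43.

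Extracellular matrix genes fell as a group, with 16 of 26 lower and 0 higher in limma (21 lower adjusted over the list alone) and a median of -0.72 (camera adjusted p = 1.36e-11). The call was lost, at adjusted p = 0.0568, with an estimated correlation, and the median was -0.60 without the 7 arrays. Thbs1, thrombospondin, changed by -1.43 ± 0.41, Col6a2 by -1.22 ± 0.26 and Col5a1 by -1.14 ± 0.17. Macrophage markers were lower in 7 of 20 and higher in 1 (11 and 2 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 4.35e-06, and adjusted p = 0.333 with an estimated correlation) and -0.43 without the 7 arrays. Gpnmb, a glycoprotein of lipid-laden macrophages, changed by -2.38 ± 0.49, Trem2, a lipid-sensing receptor, by -1.52 ± 0.30 and Mpeg1, perforin-2, by -1.45 ± 0.32. The member that rose was Cd14, the lipopolysaccharide co-receptor, at 0.56, which lies outside the rule and was chosen after its value was seen. Gpnmb, with the 7 arrays left out, stood at -1.86 (adjusted p = 0.0539).

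Inflammatory mediators were lower in 8 of 19 and higher in 1 (10 and 1 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.00150, and adjusted p = 0.276 with an estimated correlation) and -0.47 without the 7 arrays. The monocyte chemokines Ccl7 at -2.58 ± 0.37, Ccl8 at -1.53 ± 0.33 and Ccl2 at -1.14 ± 0.27 fell, as did Saa3, an acute-phase apolipoprotein, at -1.57 ± 0.48. The B-cell chemokine Cxcl13 rose by 1.13 (chosen after its value was seen). Without the 7 arrays Saa3 (-0.85, adjusted p = 0.447), Ccl8 (-1.42, adjusted p = 0.0505) and Ccl2 (-1.02, adjusted p = 0.0970) lost their calls, as did Thbs1 (-1.33, adjusted p = 0.0619) and Uqcrc2 (0.41, adjusted p = 0.164) of the lists above. Fat-mass-associated adipokines fell in 3 of 11 (1 higher and 5 lower adjusted over the list alone), with a median of -0.27 (camera adjusted p = 0.00752, and adjusted p = 0.333 with an estimated correlation). These were Sfrp5, Lep and Trp53inp2, the last of which encodes a nuclear and autophagy protein and no secreted factor, at -2.13 ± 0.24. The call of this list was lost without the 7 arrays (median -0.16, adjusted p = 0.0919), and the median turned to 0.04 (adjusted p = 0.106) with the marker score as a covariate. Cell cycle genes were lower in 1 of 14 (3 adjusted over the list alone), Mcm5 of the replicative helicase at -0.67 ± 0.20 (-0.71 and adjusted p = 0.113 without the 7 arrays), with a median of -0.40 (camera adjusted p = 0.00110, and adjusted p = 0.170 with an estimated correlation).

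Mesothelial markers rose in 3 of 10, with the same count adjusted over the list alone and a median of 0.53 (camera adjusted p = 0.0233, and adjusted p = 0.341 with an estimated correlation). With the number class as a block the call was lost at adjusted p = 0.0557, and within the classes the median was 0.26, 0.59, 0.99 and 1.01. Upk3b, a uroplakin of the mesothelial surface, rose by 1.29 ± 0.36. Epididymis and testis markers were higher in 2 of 11 (3 adjusted over the list alone), with a median of 1.39 (camera adjusted p = 0.0152, adjusted p = 0.537 with an estimated correlation and adjusted p = 0.0557 with the number class as a block). Within the classes that median was 2.80, 0.25, 1.04 and 1.27, and without the 7 arrays it was 0.27 (adjusted p = 0.329).

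The other lists did not pass in DR against AL, although single members did. Some of them passed under an alternative, cytosolic ribosomal proteins with the authors' processed values, autophagy and lysosome with no probe filter and with fry, brown and beige adipocytes and skeletal muscle markers with fry, and erythrocyte markers with fry and without the 7 arrays. Glycolysis and glucose uptake (median 0.15, adjusted p = 0.392) held 4 higher and 1 lower of 15 (4 and 2 adjusted over the list alone). The lower member, Pfkp at -1.33 ± 0.22, is a phosphofructokinase isoform whose paralogue Pfkl rose by 0.73 ± 0.14. Lipolysis (0.26, adjusted p = 0.814) held G0s2, an inhibitor of triglyceride lipase, at -1.19 ± 0.18 and Hcar2, an anti-lipolytic receptor, at 1.01 ± 0.32 among 8 genes (4 higher and 2 lower adjusted over the list alone). Cholesterol biosynthesis (-0.21, adjusted p = 0.307) held 2 lower of 16 in either adjustment, Hsd17b7 at -0.88 ± 0.19 and Sc5d at -0.63 ± 0.21. Leaving out the 7 arrays, that list passed at -0.29 (adjusted p = 0.0164). ATF4 targets and amino acid synthesis (-0.24, adjusted p = 0.547) held 1 higher and 3 lower of 15 (3 and 4 adjusted over the list alone), among them Chac1, a glutathione-degrading enzyme, at 2.02 ± 0.27 and Ddit3 at -0.77 ± 0.21. NRF2 targets and antioxidants held 2 higher and 1 lower of 16 in either adjustment, with Gsta4 at 1.43 ± 0.21 and Sod3 at -0.87 ± 0.21. Its median of -0.03 differed in sign from its mean of 0.02 (adjusted p = 0.875). Insulin, IGF1 and FOXO signalling (0.37, adjusted p = 0.0640) held 3 higher and 1 lower of 14 (5 and 1 adjusted over the list alone), with Akt2 at 0.86 ± 0.21 and Igfbp5 at -0.93 ± 0.22. Leaving out the 7 arrays, the list passed at 0.28 (adjusted p = 0.0403).

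Brown and beige adipocyte genes (median 0.40, adjusted p = 0.0761) held 2 higher of 9 in either adjustment, Ppargc1b at 1.19 ± 0.25 and the lipid-droplet protein Cidea at 1.12 ± 0.24. Ucp1, the thermogenic uncoupler, was detected on 0 arrays. Skeletal muscle markers (-0.37, adjusted p = 0.187) held 2 lower of 6 in either adjustment, Pvalb, a calcium buffer detected on no DR array, at least 2.81-fold lower and Acta1 at -1.44 ± 0.42. Endothelial markers (-0.02, adjusted p = 0.302) held 2 lower of 14 in either adjustment, Cldn5 at -0.89 ± 0.24 and Cdh5 at -0.85 ± 0.22. Autophagy and lysosome (-0.13, adjusted p = 0.187) held 2 lower of 24 in either adjustment, Ctsa at -0.85 ± 0.18 and Map1lc3a at -0.84 ± 0.22. Single members passed over all genes tested in cytosolic ribosomal proteins (Rpl22 at 0.58 ± 0.19 of 27, list median 0.05, adjusted p = 0.284), mTOR pathway components (Rictor at 0.47 ± 0.15 of 17, 0.10, adjusted p = 0.559), hepatocyte markers (Apoc3 at 0.99 ± 0.27 of 5, 0.45, adjusted p = 0.284) and adipocyte markers (Lep of 16, 0.11, adjusted p = 0.814, and passing at 0.29, adjusted p = 0.0447, with the marker score as a covariate). Adjusted over the list alone these counts were 0, 0, 1 and 1. Further members no longer past the threshold without the 7 arrays were Igfbp5 (-0.57, adjusted p = 0.204), Sc5d (-0.38, adjusted p = 0.314), Rpl22 (0.35, adjusted p = 0.406) and Rictor (0.52, adjusted p = 0.0517). Ctsa (-0.69, adjusted p = 0.0570), Map1lc3a (-0.86, adjusted p = 0.0795), Apoc3 (0.92, adjusted p = 0.0613) and Acta1 (-1.08, adjusted p = 0.227) were not past it either. In 6 lists limma called 0 members over all genes tested, namely fatty acid beta-oxidation (0.13, adjusted p = 0.284, and passing at 0.28, adjusted p = 0.0232, with the marker score as a covariate), endoplasmic reticulum chaperones (-0.15, adjusted p = 0.392), lymphocyte (-0.14, adjusted p = 0.320), fibroblast and progenitor (-0.15, adjusted p = 0.307) and erythrocyte markers (0.39, adjusted p = 0.133, 2 higher of 3 adjusted over the list alone, and passing at 0.56, adjusted p = 0.0234, without the 7 arrays) and the innate interferon response (-0.18, adjusted p = 0.386).

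**Figure D2:**
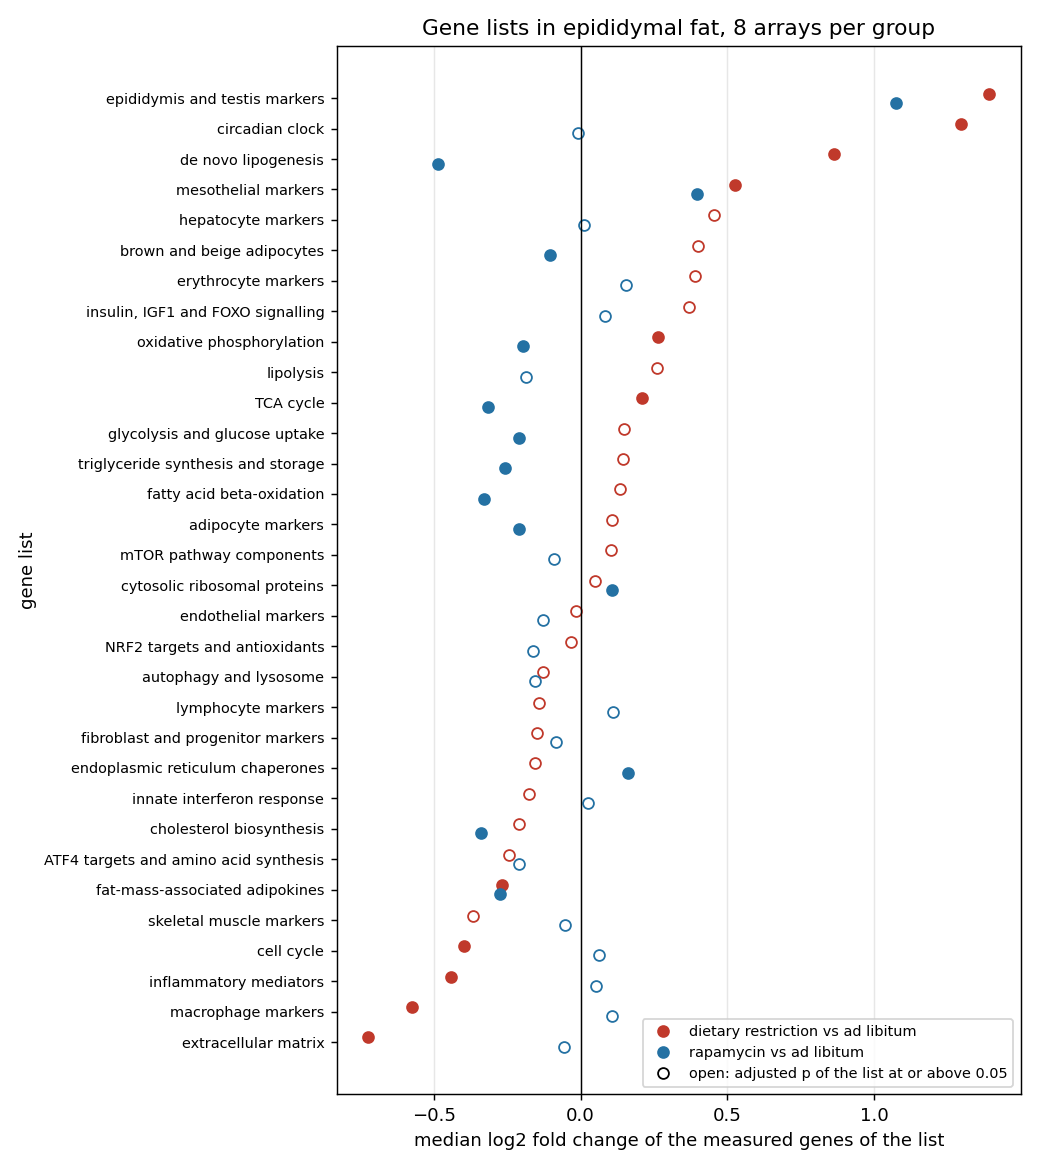
Median log2 fold change of each of the 32 gene lists for DR against AL (red) and Rapa against AL (blue), with open symbols where camera's adjusted p is 0.05 or above. The circadian clock median is 1.30 under DR and -0.01 under Rapa, and the extracellular matrix median is -0.72 and -0.06.

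Rapamycin lowered a small set of genes. Cox8b, the cytochrome c oxidase subunit of muscle and brown fat, fell from 8.87 ± 0.56 in AL to 6.66 ± 0.44 in Rapa (SD, n = 8 each), a log2 fold change of -2.22 ± 0.24 (SE, adjusted p = 1.24e-05), with 8 of 8 Rapa arrays below every AL array. Acta1, skeletal muscle actin, changed by -2.52 ± 0.42 (adjusted p = 0.00467), Mogat2, which acylates monoacylglycerol towards triglyceride, by -1.89 ± 0.26 (adjusted p = 7.55e-04). Serpina3b, a serine protease inhibitor, changed by -1.69 ± 0.22 (adjusted p = 2.91e-04). Cyp2e1 fell from 13.79 ± 0.32 to 11.99 ± 1.19, and Acss2 changed by -1.19 ± 0.22 (adjusted p = 0.0121).

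Between Rapa and AL 15 of 9836 genes differed in limma, 15 lower and 0 higher (23 probes), while 945 genes had an unadjusted p under 0.05. The rest of the named genes were C6, a complement component, at -2.19 ± 0.39 (adjusted p = 0.00964), Kcne1l, a potassium channel subunit, at -1.61 ± 0.31 (adjusted p = 0.0209), Aldh1l1, a folate enzyme, at -1.16 ± 0.23 (adjusted p = 0.0342) and Gpc1, a heparan sulfate proteoglycan, at -1.12 ± 0.17 (adjusted p = 0.00229). The remaining 5, outside the rule and chosen after their values were seen, were Aldh1a7 at -1.11, Fhit at -1.04, P2rx5 at -0.90, Ugt1a6b at -0.84 and Aldh5a1 at -0.75. C6, Mogat2 and Acss2 have 2 kept probes each, of which 1 passed. All 15 genes were lower within each of the 4 number classes, whose arrays had also given the calls. Within single classes, with 2 arrays per group, limma called between 0 and 2 genes.

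With the number class as a block 154 genes passed, 44 higher and 110 lower, the 15 among them. With the authors' score 18 passed, 3 higher and 15 lower. Leaving out the 7 arrays, 21 passed, 7 of them among the 15, and Acta1 (-2.16, adjusted p = 0.0508), Cyp2e1 (-1.66, adjusted p = 0.0718), Acss2 (-1.12, adjusted p = 0.0595) and Aldh1l1 (-0.97, adjusted p = 0.0595) were no longer past the threshold. The count was 8 without AL2 or without AL7, 9 without AL4, 23 without AL6 and 36 without AL1. Genes fixed in advance did not pass, among them Lep at -0.18 ± 0.13 (adjusted p = 0.681), Adipoq at -0.21 (adjusted p = 0.676) and Fasn at -0.21 (adjusted p = 0.889). The same holds for Pparg at -0.12 (adjusted p = 0.880), Pck1 at -0.57 (adjusted p = 0.672) and Igf1 at -0.16 (adjusted p = 0.827). Of the drug's own pathway, Mtor stood at 0.31 (adjusted p = 0.586), Eif4ebp1, the translation repressor that mTOR phosphorylates, at -0.83 (adjusted p = 0.336) and Fkbp1a, the protein that binds rapamycin, at -0.26 (adjusted p = 0.622). Under DR these fixed genes did not pass either where not given above, with Adipoq at -0.03 (adjusted p = 0.924), Pparg at 0.50 (adjusted p = 0.111), Igf1 at -0.28 (adjusted p = 0.403), Mtor at 0.43 (adjusted p = 0.119), Eif4ebp1 at -0.08 (adjusted p = 0.909) and Fkbp1a at -0.30 (adjusted p = 0.265). Of these, Mtor passed under DR with the number class as a block (adjusted p = 0.0134), and Pparg passed without the 7 arrays (0.76, adjusted p = 0.0150). Rps6kb1 has no named probe on the array.

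Lists of energy and lipid metabolism shifted downwards under rapamycin by small amounts, with few members passing singly. With an estimated correlation oxidative phosphorylation kept its call (adjusted p = 0.0491), and the TCA cycle, beta-oxidation, lipogenesis and cholesterol lists lost theirs (adjusted p = 0.147 each). The TCA cycle list had a median of -0.32 over 19 genes (camera adjusted p = 1.49e-05), fatty acid beta-oxidation -0.33 over 18 (adjusted p = 4.77e-05), de novo lipogenesis -0.49 over 14 (adjusted p = 9.56e-05). Cholesterol biosynthesis had -0.34 over 16 (adjusted p = 1.48e-04) and oxidative phosphorylation -0.20 over 38 (adjusted p = 8.97e-05). Over all genes tested limma called Acss2 in lipogenesis and 0 members in the others. Adjusted over the list alone 2, 4, 5, 4 and 0 were lower, in that order. Among the members named from DR other than Acss2, none of which passed here, Pcx stood at -0.80 ± 0.21, Dlat at -0.38 ± 0.15, Ndufs7 at -0.30 ± 0.14, Cpt2 at -0.27 ± 0.19 and Elovl6 at -0.01 ± 0.35. Pcx passed with the number class as a block (adjusted p = 0.0443). The medians without the 7 arrays were -0.28, -0.20, -0.43, -0.61 and -0.25, and all 5 stayed past the threshold. Within the 4 classes the median was below 0 throughout, except for cholesterol biosynthesis in numbers 4 and 8 (0.08).

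A further 5 lists shifted downwards and 4 upwards, and each of these calls was lost with an estimated correlation. Triglyceride synthesis and storage had a median of -0.26 (adjusted p = 2.94e-04, and adjusted p = 0.196 with an estimated correlation), with 0 members called in limma and 3 lower adjusted over the list alone. Its median was -0.05 (adjusted p = 0.0726) when the 7 arrays were left out. Glycolysis and glucose uptake stood at -0.21 (adjusted p = 0.0151, and 0.196 with an estimated correlation), brown and beige adipocytes at -0.10 (adjusted p = 0.00991, and 0.147), where Cox8b passed and 2 were lower adjusted over the list alone. Fat-mass-associated adipokines stood at -0.27 (adjusted p = 0.0370, and 0.396) and adipocyte markers at -0.21 (adjusted p = 0.00141, and 0.370), with 1 lower adjusted over the list alone. Without the 7 arrays these 4 stood at -0.21 (adjusted p = 0.0537), -0.37 (0.141), -0.10 (0.730) and, with the direction turned, 0.04 (0.546). Cytosolic ribosomal proteins stood at 0.11 (adjusted p = 2.94e-04, and 0.196 with an estimated correlation), endoplasmic reticulum chaperones at 0.16 (adjusted p = 0.0107, and 0.196). Mesothelial markers stood at 0.40 (adjusted p = 0.0374, and 0.370) and epididymis and testis markers at 1.08 (adjusted p = 0.00523, and 0.434), with 0 members of these 4 lists called in limma in either adjustment. Without the 7 arrays these 4 stood at 0.01 (adjusted p = 0.366), 0.09 (0.339), 0.27 (0.0726) and, with the direction turned, -0.34 (0.366). With the number class as a block the mesothelial call was lost (adjusted p = 0.0838).

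The other lists did not pass under rapamycin, but some did under an alternative. Macrophage markers passed without the 7 arrays (0.30, adjusted p = 0.0324) and with the marker score as a covariate (0.23, adjusted p = 0.00241), as did insulin, IGF1 and FOXO signalling (0.30, adjusted p = 0.0128, and 0.21, adjusted p = 0.0305). Autophagy and lysosome passed with median scaling and with no probe filter, skeletal muscle markers with no probe filter and with fry, and inflammatory mediators only where the 7 arrays were left out and the class block was fitted together. The immune and matrix lists that fell under DR stood at 0.11 for macrophage markers (adjusted p = 0.0755), 0.05 for inflammatory mediators (adjusted p = 0.146) and -0.06 for extracellular matrix, whose mean was 0.00144 (adjusted p = 0.984). The circadian clock had a median of -0.01 and a mean of 0.04 (adjusted p = 0.658), the mTOR pathway components stood at -0.09 (adjusted p = 0.658), and autophagy and lysosome at -0.16 (adjusted p = 0.146). Insulin, IGF1 and FOXO signalling stood at 0.08 (adjusted p = 0.475), lipolysis at -0.19 (adjusted p = 0.222), ATF4 targets at -0.21 (adjusted p = 0.243), NRF2 targets at -0.16 (adjusted p = 0.444) and cell cycle at 0.06 (adjusted p = 0.566). Marker lists stood at 0.11 for lymphocytes (adjusted p = 0.484), -0.08 for fibroblasts and progenitors (adjusted p = 0.835), -0.13 for endothelium (adjusted p = 0.160), -0.05 for skeletal muscle (adjusted p = 0.146), where Acta1 passed, and 0.15 for erythrocytes (adjusted p = 0.222). The hepatocyte list, where Cyp2e1 passed, had a median of 0.01 and a mean of -0.30 (adjusted p = 0.403). The innate interferon response had a median of 0.02 and a mean of -0.01 (adjusted p = 0.984).

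**Figure D3:**
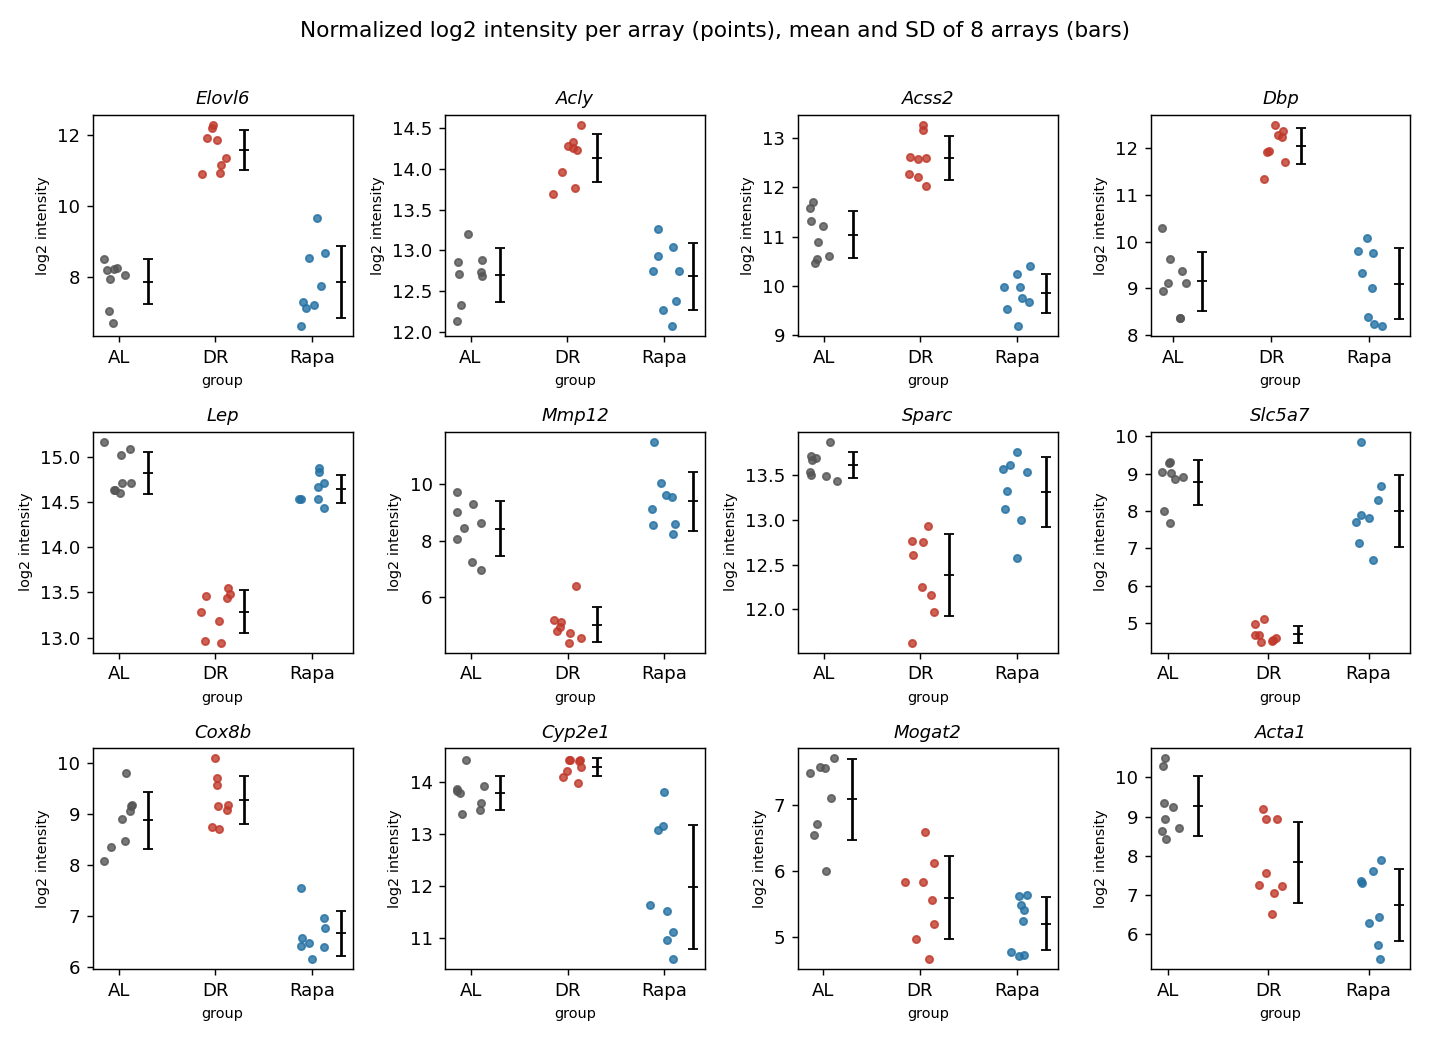
Log2 intensity of 12 named genes on each array (points) with mean and SD of the 8 arrays of AL, DR and Rapa. Elovl6 averages 11.58 in DR and 7.86 in both AL and Rapa, and Cox8b averages 6.66 in Rapa, 8.87 in AL and 9.27 in DR.

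Set directly against rapamycin, restricted animals had higher lipogenic, mitochondrial and clock genes and lower macrophage and matrix genes, the macrophage list at adjusted p = 0.116 with an estimated correlation. Elovl6 was higher in DR by 3.72 ± 0.35 (SE, n = 8 each, adjusted p = 6.73e-08), and Acacb, the acetyl-CoA carboxylase that restrains fatty acid import into mitochondria, by 2.91 ± 0.32 (adjusted p = 7.61e-07). Mmp12 was lower in DR by a log2 fold change of -4.37 ± 0.41 (adjusted p = 6.73e-08), and Rgs1, a regulator of G-protein signalling in leukocytes, by -2.83 ± 0.40 (adjusted p = 2.37e-05). Cox8b was higher by 2.62 ± 0.24 (adjusted p = 5.39e-08), and Acss2, which rose under DR and fell under rapamycin, by 2.74 (adjusted p = 3.99e-09).

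The direct comparison called 1123 genes, 578 higher and 545 lower in DR (1723 probes, 907 by at least 1.5-fold). The rest of the named genes were Acsm3 at 3.71 ± 0.41, Defb20 at 2.99 (adjusted p = 0.0268) and Dbp at 2.94 ± 0.29 on the higher side, and Slc5a7, at least 6.31-fold lower in DR, Rnase2a at -3.04 and Sfrp5 at -2.87 ± 0.31 on the lower side. With the number class as a block 1887 genes passed, the 1123 among them, and within the classes between 98.7% and 99.6% of the 1123 kept their sign. That share too is raised by calling the genes on the same arrays. Without the 7 arrays 763 passed, 596 of them among the 1123.

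Of the 14 lists called in this comparison, 6 kept their call with an estimated correlation. De novo lipogenesis was higher in DR in 10 of 14 (11 higher and 1 lower adjusted over the list alone), with a median of 1.38 (camera adjusted p = 4.08e-12, and adjusted p = 0.00356 with an estimated correlation). Oxidative phosphorylation was higher in 14 of 38 (22 adjusted over the list alone), with a median of 0.46 (adjusted p = 4.08e-12, and adjusted p = 1.83e-04 with an estimated correlation). The TCA cycle was higher in 8 of 19 (14 higher and 1 lower adjusted over the list alone), with a median of 0.58 (adjusted p = 3.24e-08, and adjusted p = 0.0453 with an estimated correlation), Pcx by 1.78 ± 0.21 and Dlat by 1.04 ± 0.15. The circadian clock was higher in 8 and lower in 2 of 12 (9 and 2 adjusted over the list alone), with a median of 1.26 (adjusted p = 8.29e-07, and adjusted p = 0.00554 with an estimated correlation). Brown and beige adipocyte genes were higher in 3 of 9 in either adjustment, with a median of 0.44 (adjusted p = 4.10e-04, and adjusted p = 0.0449 with an estimated correlation), namely Cox8b, Cidea at 1.67 ± 0.24 and Ppargc1b at 1.28 ± 0.25, and the median was 0.22 (adjusted p = 0.0283) without the 7 arrays. Extracellular matrix was lower in 14 of 26 (18 adjusted over the list alone), with a median of -0.70 (adjusted p = 4.08e-12, and adjusted p = 0.0449 with an estimated correlation), Sparc by -0.93 ± 0.18.

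The other 8 calls were lost with an estimated correlation. Macrophage markers were lower in DR in 9 of 20 (15 adjusted over the list alone) with a median of -0.70 (adjusted p = 8.48e-09, and adjusted p = 0.116 with an estimated correlation). Inflammatory mediators were lower in 7 of 19 (1 higher and 10 lower adjusted over the list alone) with -0.53 (adjusted p = 2.96e-05, and 0.0708), Ccl7 by -2.63 ± 0.37 and Ccl8 by -2.16 ± 0.33. Cell cycle genes were lower in 4 of 14 (8 adjusted over the list alone) with -0.57 (adjusted p = 1.79e-04, and 0.0708 with an estimated correlation). Triglyceride synthesis and storage was higher in 7 of 15 (9 adjusted over the list alone) with a median of 0.50 (adjusted p = 1.72e-05, and 0.108 with an estimated correlation), Pck1 by 2.16 ± 0.40 and Gpam by 1.57 ± 0.16, and the median was 0.81 without the 7 arrays. Fatty acid beta-oxidation was higher in 5 of 18 (8 adjusted over the list alone) with 0.36 (adjusted p = 3.25e-05, and 0.108), Cpt2, the inner-membrane carnitine transferase, by 0.71 ± 0.19. Glycolysis and glucose uptake was higher in 4 and lower in 1 of 15 (6 and 1 adjusted over the list alone) with 0.35 (adjusted p = 0.0244, and 0.179), the lower member again being Pfkp at -0.99 ± 0.22. Adipocyte markers were higher in 4 and lower in 1 of 16 (5 and 1 adjusted over the list alone) with 0.46 (adjusted p = 0.0323, and 0.588), the lower member being Lep at -1.35 ± 0.13. Endoplasmic reticulum chaperones were lower in 4 of 15 in either adjustment with -0.22 (adjusted p = 0.0143, and 0.166). These last lists, without the 7 arrays, stood at 0.34 (adjusted p = 0.117) and -0.26 (adjusted p = 0.165). Marker lists of epididymis and testis (0.32, adjusted p = 0.496) and mesothelium (0.29, adjusted p = 0.373) did not pass between the treatments, and cholesterol biosynthesis, with 4 higher and 1 lower of 16 in either adjustment, did not either (0.12, adjusted p = 0.235). Under an alternative the epididymis and testis markers passed with no probe filter, adipokines with no probe filter, the mean of probes and fry, hepatocyte markers with median scaling and fry, lymphocyte markers with fry, and the innate interferon response only where the 7 arrays were left out and the class block was fitted together.

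DR and rapamycin were compared with the same AL arrays, which by itself makes their effects correlate. Across 9836 genes, which are not independent replicates, the fold changes of the treatments correlated at r = 0.44 (Spearman rho 0.36), and unchanged groups simulated against the same arrays gave r = 0.492 ± 0.208 (SD, 100 simulations). With the AL arrays split between the comparisons r was 0.248 (range 0.107 to 0.352 over 70 splits). The covariance was 0.0671 against 0.0309 ± 0.0219 in the simulations, a difference of 0.0363. Leaving out the 7 arrays gave r = 0.198.

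Calls were shared for 9 genes. Lower under both treatments were 8, namely Gpc1 (-1.29 under DR and -1.12 under Rapa), Ugt1a6b (-0.83 and -0.84), Acta1 (-1.44 and -2.52), C6 (-1.49 and -2.19), Kcne1l (-1.43 and -1.61), Mogat2 (-1.49 and -1.89), Serpina3b (-1.08 and -1.69) and Fhit (-0.78 and -1.04). Their number compares with 0.974 for independent lists and a mean of 0.02 (highest 2) in the simulations. Neither value decides whether the overlap exceeds what the shared AL arrays give. Independence ignores those arrays, and the simulated groups were unchanged and so give few calls to share. Limma called 0 genes higher under both, and Acss2 went in opposite directions (1.55 and -1.19, against 0.779 for independent lists). With the AL arrays split, the shared calls averaged 2.17 (highest 8), and with the number class as a block they numbered 79. Of the 1150 genes called under DR, 791 (68.8%) had the same sign under rapamycin, a share that the shared AL arrays also raise.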

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

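In this part the tests of the marker score against the adipocyte markers, of induction by treatment and of changes without the 7 arrays were chosen after the result was seen, as were the use of number classes and the splits balanced over them.

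The median of the epididymis and testis markers lay above 6 on 7 of the 16 treated arrays and on 0 AL arrays, although DR7 carried a set of epididymal genes (Lcn8 at 11.58, Gpx5 at 9.77, Adam7 at 9.45), AL7 testis genes (Prm1 at 11.72, Ldhc at 9.69, Tnp1 at 9.34) and AL6 Defb42 at 12.49. The marker score of 9 treated arrays lay at or below that of the highest AL array. Among them were Rapa3, Rapa4 and Rapa5, where neither Wfdc10 nor Adam7 was detected, which argues against induction in every rapamycin-treated animal. For DR this stays open, since the 9 include DR7, and Wfdc10 and Adam7 were detected on 8 of 8 DR arrays (5 and 4 AL arrays). Induction in some animals stays open for both treatments. Tissue of the epididymis or testis carried over at dissection could account for the pattern, since the marker score fell as the adipocyte median rose within groups (Pearson r = -0.772, permutation p = 0.00342 over 100000 shuffles, Spearman rho = -0.473, p = 0.0395). That relation rests on Rapa8 and Rapa6, without which r was -0.489 (permutation p = 0.141). Within the number classes r was -0.912, -0.993, 0.355 and -0.797. A class holds 2 arrays of every group, so each of these values rests on a single difference per group and carries little weight. Of the 1150 calls of DR against AL, 98.3% kept more of their fold change than they lost without the 7 arrays. That share does not decide how far carry-over accounts for the calls. The epididymal genes Defb20 (3.80 to 2.36) and Spag11b (2.85 to 2.18) are among those that kept it. The omission leaves DR7, AL6 and AL7 in, and the arrays left had also given the calls. The 20 others include 2 genes of the epididymis list, and Defb37, which is known from the epididymis but not in that list.

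Lists of energy and lipid metabolism were lower under rapamycin by small medians. Dimmer or brighter arrays stay open as an explanation. Although 6 of 6 lists had a median below 0 within at least 3 of the 4 number classes, every class holds arrays of each group and brightness still differs within a class. Carry-over of epididymis or testis tissue cannot be told apart from an effect of the drug for the set, since 5 of 6 lists kept more of their median than they lost without the 7 arrays and the triglyceride list went from -0.26 to -0.05. An effect of rapamycin stays open for the lists, and with an estimated correlation 1 list passed under rapamycin in all.

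Other splits of the arrays were counted with 100 splits per comparison, the real split included. For DR against AL, 1 split gave 1150 genes or more and the highest other gave 1, and 4 gave 11 lists or more with a highest of 13. For Rapa against AL, 1 split gave 15 genes or more with a highest other of 13, and 4 gave 14 lists or more with a highest of 15. For DR against Rapa, 1 split gave 1123 genes or more and the highest other gave 562. The split with 562 kept 7 of the 8 arrays of a treatment on the same side, and so follows the treatment. For the lists of that comparison, 17 splits gave 14 or more with a highest of 18. The median number of lists called in the other splits was 3 for DR against AL, 6 for Rapa against AL and 7 for DR against Rapa. For Rapa against AL a split with 4 arrays of each treatment on each side called 14. Camera at the preset correlation can thus call lists without the real grouping, so its p-values for lists are not to be taken at face value.

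Those splits ignore the number classes, over which the real split is balanced. In 100 splits per comparison with 2 arrays of every class on each side, 1 gave as many genes as the real split in each comparison, with a highest other of 345 for DR against AL, 5 for Rapa against AL and 500 for DR against Rapa. The splits with 345 and 500 kept 7 of the 8 arrays of a treatment together. As many lists as in the real split were called in 20 splits for DR against AL (11 lists, highest other 13), 7 for Rapa against AL (14, highest 15) and 17 for DR against Rapa (14, highest 19). The median number of lists in the other balanced splits was 5, 7 and 10, in that order. Chance can thus be excluded for the number of genes in DR against AL and in DR against Rapa under both kinds of split. For Rapa against AL, a split with 4 arrays of each treatment on each side gave 13 genes against the real 15. Chance is therefore not excluded for that count. For the number of lists chance cannot be excluded between DR and Rapa under either kind, nor for Rapa against AL once the classes are balanced. Many splits of DR against Rapa with as many lists also kept 6 or 7 arrays of a treatment together. However, a balanced split with 4 arrays of each treatment on each side gave 15 lists there. For DR against AL with balanced classes, most splits with as many lists kept 6 or 7 of the 8 arrays of a treatment together. Such splits partly follow the treatment, so their number does not decide whether chance gives as many lists.

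A value far from the others of its group was looked for by Dixon's ratio of gap to range at its 95% critical value. This was done in 435 tests, each on a list median, a named gene or an array measure over the 8 arrays of a group. It was met in 31, where chance, at about 1 in 20, gives 21.8. The tests overlap, since list medians and their member genes share values, so these numbers do not measure an excess. AL6, DR5 and Rapa8 had 6 each, AL1 had 4, and DR7 and Rapa7 had 2 each. The values below are log2 intensities, with the nearest array of the group in brackets.

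Among list medians, DR5 stood at 9.81 (10.71) for triglyceride synthesis and storage, at 9.38 (9.79) for lipolysis and at 6.42 (5.51) for skeletal muscle markers. Rapa8 stood at 8.54 (9.31) for fatty acid beta-oxidation and at 9.14 (9.98) for extracellular matrix, and Rapa6 at 9.82 (9.48) for autophagy and lysosome. AL6 stood at 9.34 (10.04) for extracellular matrix and at 7.85 (6.56) for skeletal muscle markers, and AL1 at 7.32 (7.77) for ATF4 targets.

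Among genes on AL arrays, AL6 stood at 7.39 (5.63) for Wfdc10, 9.28 (10.17) for Col6a2, 11.10 (11.75) for Col5a1 and 5.47 (6.73) for Pvalb. AL1 stood at 8.25 (5.53) for Adam7, 7.66 (8.59) for Pcx and 7.54 (6.45) for Per3, AL3 at 11.03 (10.67) for Pkm and AL5 at 8.39 (7.13) for Thbs1.

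Among genes on DR arrays, DR5 stood at 9.81 (10.71) for Slc27a1, which is the triglyceride list's median gene there, 8.71 (7.89) for Hsd17b7 and 6.82 (6.41) for Mcm5. DR7 stood at 6.41 (5.19) for Mmp12 and 6.04 (5.15) for Rgs1, DR4 at 6.12 (5.33) for Tph2 and DR2 at 5.61 (4.88) for Ccl2. Among genes on Rapa arrays, Rapa8 stood at 6.28 (7.58) for Aldh1l1, 6.77 (7.66) for Pcx, 13.89 (14.63) for Hba-a1 and 12.79 (13.44) for Adipoq, and Rapa7 at 6.49 (5.35) for Spag11b and 10.75 (10.08) for Gpc1.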

How the results depend on the processing

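The number class block, the marker score covariate, their combination and omission of the 7 arrays, alone or with the class block, were chosen after the result was seen; the other alternatives were chosen before. Named genes stayed on their side of the threshold in 4650 comparisons with an alternative, passed it anew in 54 and no longer passed in 316, and gene lists in 1372, 50 and 90. Direction turned in 0 of 3935 comparisons for called named genes and in 29 of 1085 for those not called, and in 6 of 620 for called lists and 66 of 898 for others. Of 82 named genes called under DR, 20 lost the call on omission of some array, of 10 under Rapa 2 and of 10 between DR and Rapa 1. Counts and correlations stayed within 1.5 times or the spread in 210 and moved in 42. Where a value moved, the cause was not tested, except that a threshold of 0.01 calls fewer genes by construction. Signal over background limits the dim genes, since the arrays detected between 28.7% and 42.4% of probes.

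Genes called in DR against AL (1150) numbered 1886 with the replicate block, 1804 with array weights, 1953 with the number class block, 2125 with the marker score and number class, 676 without the 7 arrays and 582 at adjusted p under 0.01. Leaving out each array gave between 914 (AL3) and 1268 (Rapa8). In Rapa against AL (15) they numbered 5 without background correction, 8 with no filter, 121 with the replicate block, 48 with array weights, 25 with the mean of probes, 154 with the number class block, 176 with the marker score and number class, 165 without the 7 arrays and with the class block, and 6 at 0.01. Leaving out each array gave between 8 (AL2, AL7) and 36 (AL1), with 9 without AL4 and 23 without AL6. In DR against Rapa (1123) they numbered 1765 with the replicate block, 1887 with the number class block, 2271 with the marker score and number class and 611 at 0.01, and between 975 (DR8) and 1218 (DR5) leaving out each array.

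Genes called under both treatments (9) numbered 2 without background correction, 58 with the replicate block, 27 with array weights, 79 with the number class block, 100 with the marker score and number class, 14 without the 7 arrays, 66 with the class block as well and 2.17 with AL split, and between 5 (AL2) and 23 (AL1) leaving out each array. The correlation of effects (0.44) was 0.198 without the 7 arrays, and between 0.347 (DR5) and 0.517 (AL1) leaving out each array. Lists called under DR (11) numbered 7 with probes detected on all arrays, which leaves 26 lists, and 3 with an estimated correlation. Under Rapa (14) they numbered 7 without the 7 arrays, 9 with the class block as well, 1 with an estimated correlation and 7 with fry, and between DR and Rapa (14) 6 with an estimated correlation.

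The adipokine median under DR (-0.27) turned to 0.0406 (adjusted p = 0.106) with the marker score and 0.0600 (0.178) with the number class as well. Under Rapa the adipocyte marker median (-0.21) turned to 0.0372 (0.546) without the 7 arrays and 0.0357 (0.622) with the class block as well, and the epididymis and testis median (1.08) to -0.34 (0.366) and -0.32 (0.502). Arrays with the same number share structure, since 19 of 24 such pairs correlated above 0.1 and 14 of 24 arrays correlated best with their own number. They were not taken as pairs because not every pair exceeded 0.1 (lowest -0.069) and no label pairs them. A BeadChip block was not run, and leaving out each array was not done for lists.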

Other observations

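Genes in the next paragraph and the test of the clock were chosen after the result was seen, and the class block they rest on was added then.

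With the number class as a block, rapamycin against AL gained further genes. Insig1, which holds back the SREBP activators of sterol synthesis, changed by -1.27 ± 0.26 (SE, n = 8 each, limma adjusted p = 0.0178, and 0.0598 without the block), and Ptger3, the anti-lipolytic prostaglandin E receptor, by -1.53 ± 0.24 (adjusted p = 0.00267, and 0.0787 without the block). Igfals, the carrier subunit of circulating IGF1, changed by -1.28 (adjusted p = 0.00145, and 0.0547 without the block) and by -1.48 under DR (adjusted p = 6.14e-06). Timp1, the inhibitor of matrix metalloproteinases, rose under rapamycin by 0.87 ± 0.22 (adjusted p = 0.0459, and 0.143 without the block) and fell under DR (-1.04, adjusted p = 0.00155). The neutrophil chemokine Cxcl1 also went in opposite directions, 1.18 ± 0.29 under rapamycin (adjusted p = 0.0458, and 0.0914 without the block) and -0.99 under DR (adjusted p = 0.0204). Its call under rapamycin was also lost when the 7 arrays were left out of the blocked fit (0.93, adjusted p = 0.0876).

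The clock genes moved in opposite directions under DR. Of the measured members, the Arntl arm (Arntl and Clock, 2 genes) had a median log2 fold change of -1.25 and the arm of Per and Dbp genes (8 genes) 1.79. A shift in the phase of the clock at the hour of collection cannot be told apart from a lasting change of the clock by restriction. The arms had been seen to part before they were compared, and the hour of collection is not given in the sources used here.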
